A study of Homo sapiens with 8 samples.

How the data were processed

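The deposited gene count table holds 60708 genes in 8 columns, each matched to a library by its title. Per the file headers, the authors made these counts with featureCounts 2.0.1 on paired reads against GENCODE release 38, without a strand option, although the labels name a stranded mRNA kit. Reads of a gene and of an antisense partner were therefore not told apart by strand. STAR 2.7.9a for alignment to GRCh38, Subread 2.0.1 and edgeR 3.34.1 are named in the submitters' processing notes. The authors also deposited log2 CPM values for 13169 genes, whose lowest count in any library was 7. These log2 CPM values lay within 0.0226 of TMM log2 CPM computed from the counts with a prior count of 2. They leave out 2839 of the genes tested here, BMP6, ESM1, BIRC3 and OAS1 among them, so the counts were the main data. Gene positions come from the count table. Groups came from the sample titles, and the treatment field that contradicts them was not used.

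Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 16008 genes (12903 protein-coding), TMM factors scaled the libraries, and a quasi-likelihood model with a mean per group was fitted over all 8 libraries, so that the groups shared one estimate of the spread. The common biological coefficient of variation was 9.91%, with 4 residual degrees of freedom and 9.21 prior ones. Tests were 2-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. They restate the test, and where a group has few counts they can lie below the counting error. Contrasts were TGF-β over control in Mock and in HSF2oe cells, HSF2oe over Mock with and without TGF-β, the difference of both TGF-β effects, and each effect averaged over the other factor. CPM values of single genes are counts scaled by TMM-adjusted library totals.

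Total counts ran from 17427645 to 34336107 per library, which puts the limit that a count of 0 allows, 3 counts, between 0.0851 and 0.195 CPM; it covers counting error only. Libraries of a group differed by 12.5 to 26.9 times the sampling noise (chi-square per degree of freedom over genes with a summed count of at least 20), so no pair looked like a single library under 2 names. Of the genes tested, those sharing many exonic bases with another gene are uncertain. The share is given for VIM, SLC43A3 and IL21R, and smaller shares, such as 13.2% for ITGA1 and 9.92% for CDH6, are not given.

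Gene lists were fixed from general knowledge before the data were examined, as were the contrasts, the named-gene rule and the first alternatives. The 27 lists are TGF-β-SMAD target genes, TGF-β ligands and receptors, EMT transcription factors and mesenchymal markers, epithelial junction and keratin genes, extracellular matrix and collagen crosslinking, actin cytoskeleton and contractile genes, integrins, cadherin superfamily, matrix proteases and inhibitors, heat shock proteins and cochaperones, heat shock factors and partners, proteasome subunits, G1-S and DNA replication, G2-M and mitosis, p53 target genes, unfolded protein and amino acid stress response, interferon-stimulated genes, inflammatory and NF-kB target genes, NRF2 and metallothionein genes, glycolysis and hypoxia genes, cholesterol synthesis, YAP-TEAD target genes, meiosis and germ cell genes, ribosomal protein genes, mitochondrially encoded genes, luminal breast epithelial markers, blood and endothelial markers. Each list's members past the threshold were counted over all genes tested and adjusted over the list alone. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. With an estimated correlation only the TGF-β and SMAD target list passed, in the TGF-β contrasts of Mock, of HSF2oe and averaged cells.

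Named genes were 12 fixed genes (among them HSF2, HSF1, SMAD7, CDH1, CDH2, FN1, VIM, SNAI1, SNAI2, MKI67 and HSPA1A); per contrast up to 6 rises and 6 falls with the largest log2 change among genes past the threshold, with a mean log2 CPM of at least 1 and the same direction in every pair of libraries of the compared groups; and up to 4 members per list with the smallest p. HSF2 was left out of the second part, and the pair condition did not apply to the averaged contrasts. Results of a few genes that the rule takes are not reported here. The other genes of the second part are all named, each with its lost calls where these apply. Shared exonic bases are given only where they are many, so smaller shares, such as 7.8% for ANK1, are not given. Of the list members, the text names mainly those whose calls held when single libraries were left out and that share few exonic bases, a choice made after their values were seen, so named list members look steadier than the lists as a whole. Over all genes that the rule takes, 486 of 630 calls held under every alternative.

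Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 CPM, RLE size factors, library totals alone, no filter beyond a total of 1 count, a filter of CPM 1 in 4 libraries, the replicate number as a block, the 4 libraries of a contrast alone, and leaving out each library in turn. A fit without one library leaves its group with a lone library, assumed to vary like the other groups. Thinning all libraries to the lowest total, and RLE and leave-one-out fits for the lists and the overlaps, were added after the data were seen. On simulated counts with 200 changed genes and 5 draws, whose number was raised after the first draw, pairwise contrasts recovered 53.1% to 58.5% of 1.5-fold changes, 89.3% to 94.3% of 2-fold changes and 99.7% to 100.0% of 4-fold changes. The contrast of both TGF-β effects recovered 16.1%, 75.8% and 97.9%. The changed genes were drawn only among those with a mean log2 CPM of at least 1. False calls made up 5.82% to 8.59% of the calls, above the 5% aimed at. In the camera test a simulated list shift of 0.5 was called in 5 of 5 draws and 0 of 130 tests of other lists were called. The simulated genes varied independently, so this cannot show how often the preset correlation gives false calls for lists of correlated genes.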

Results

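Gene expression was measured by RNA sequencing in HS578T, an established human breast cancer cell line, in 4 groups of 2 libraries. The cells received 25 µg of a plasmid encoding green fluorescent protein (Mock) or the transcription factor HSF2 (HSF2oe). After another 24 h they were kept for 24 h in assay medium alone (control) or in medium with 10 ng/ml TGF-β1, a cytokine that signals through SMAD transcription factors (TGF-β). The design text calls the libraries of a group biological replicates, and the title of the series names proliferation and invasion as the processes of interest. Total gene counts were 25241347 and 34336107 in the Mock control libraries, 17427645 and 23726768 with Mock TGF-β, 28012966 and 29112540 with HSF2oe control and 32934381 and 23232467 with HSF2oe TGF-β. A treatment field of the sample labels lists DMSO for every Mock library and TGF-β1 for every HSF2oe library, against the titles and the design text, so the groups follow the titles.

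HSF2, a member of the heat shock factor family (ENSG00000025156.13, chromosome 6, 122399551 to 122433119, plus strand, GRCh38), was far higher in every HSF2oe library than in any Mock library. Its TMM-normalised CPM were 8.36 and 6.44 in Mock control, 5.4 and 5.76 in Mock TGF-β, 937 and 616 in HSF2oe control and 780.3 and 489 in HSF2oe TGF-β. The log2 fold change of HSF2oe over Mock was 6.72 ± 0.27 (± standard error throughout) without TGF-β and 6.83 ± 0.28 with it (adjusted p = 3.25e-08 and 4.48e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HSF1, the main heat shock factor, differed by 0.03 ± 0.09 and -0.01 ± 0.09 and did not pass the test (adjusted p = 0.896 and 0.978, same test). HSF2 counts hold plasmid and endogenous transcripts together, and the design does not separate HSF2 protein from other differences between the plasmids. FN1, which encodes fibronectin, was the most abundant gene in every library, taking 2.71% to 4.65% of the counts. The first principal component of log2 CPM (36.9% of the variance) put every HSF2oe library above every Mock library. On the second (26.8%), both TGF-β libraries of a transfection lay below both of its control libraries. Both components mixed the factors. TGF-β libraries also lay below the controls of their transfection on the first, and HSF2oe libraries lay below the Mock libraries of the same treatment on the second. TMM factors ran from 1.03 to 1.11 in control libraries and from 0.857 to 1.01 in TGF-β libraries, so scaling moved with the treatment.

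**Figure D1:**
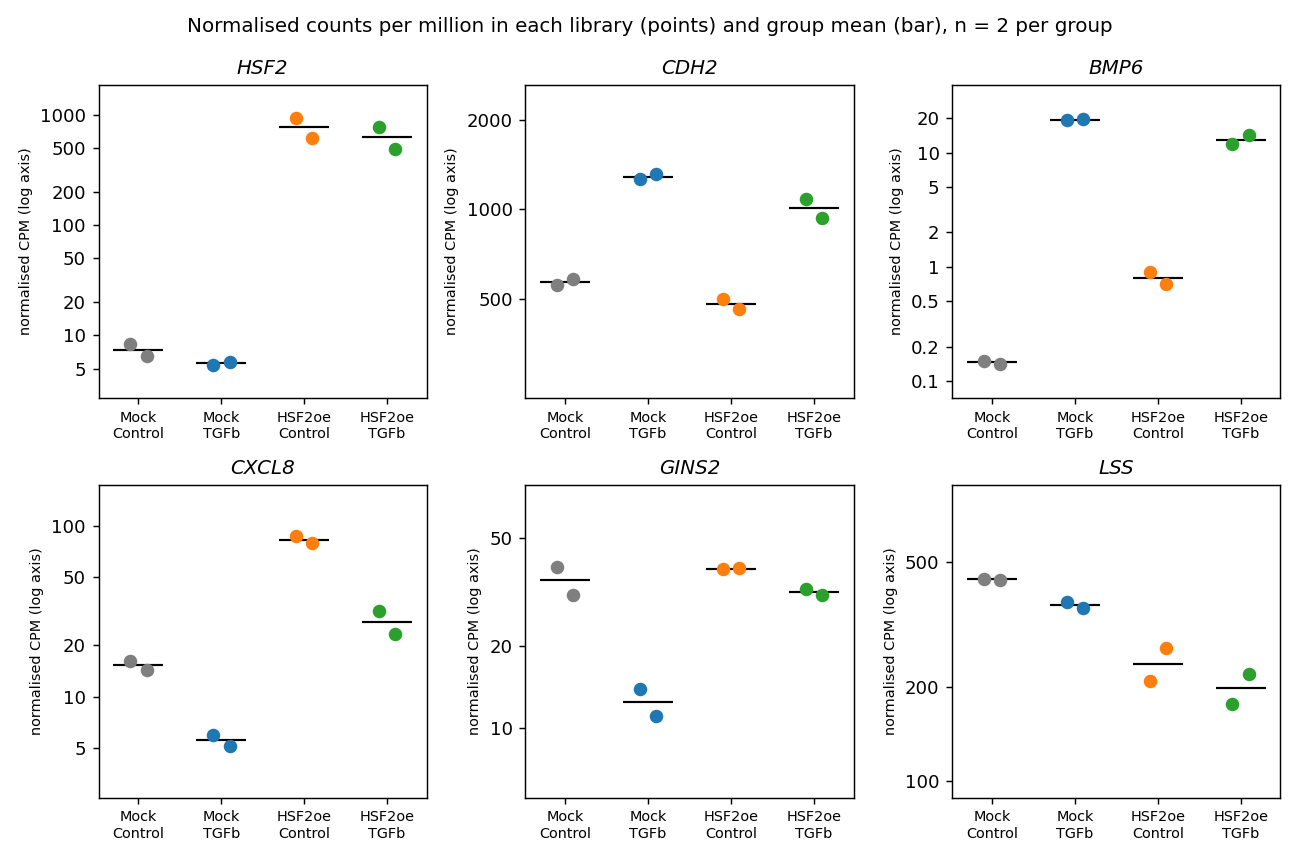
TMM-normalised CPM (log axis) of 6 genes in each of the 8 libraries, by group; points are libraries and bars are group means. HSF2 was at 5.4 to 8.36 CPM in the Mock libraries and at 489 to 937 CPM in the HSF2oe libraries.

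The Mock libraries showed how GFP-transfected cells responded to 24 h of TGF-β1. CDH2 (ENSG00000170558.10, chromosome 18, 27932879 to 28177946, minus strand), encoding N-cadherin, rose from 569 ± 20.2 to 1292 ± 33.1 CPM (mean ± SD, n = 2 each), a log2 fold change of 1.18 ± 0.11. BMP6 (ENSG00000153162.9, chromosome 6, 7726099 to 7881728, plus strand), a secreted bone morphogenetic protein, went from 4 and 5 counts to 296 and 398 counts, a log2 rise of 7.02 ± 0.26. With so few starting counts, the standard error of BMP6 may lie below the counting error. The transcription factor genes FOXS1 and SNAI1 rose by 3.73 ± 0.34 and 2.49 ± 0.33, and the sialyltransferase gene ST6GAL2 by 4.06 ± 0.24. The collagenase gene MMP13, at 0.0749 CPM or less in Mock control, rose by 6.44 ± 0.50, EGR2 by 4.02 ± 0.48, or 6.22 without Mock control 2, and KIAA1755 by 3.73 ± 0.49. The MMP13 level in Mock control lay below the limit that a count of 0 allows (0.112 and 0.0851 CPM), so the size of its rise is uncertain. Large falls included IFIT1 (-2.61 ± 0.49, a call lost without Mock TGF-β 2 at an adjusted p of 0.0508) and SLC43A3 (-2.48 ± 0.35, 29.9% of its exonic bases shared with another gene). They also included LINC01085 (-3.44 ± 0.40), SECTM1 (-2.61 ± 0.24), RIBC2 (-2.61 ± 0.36) and FAM111B (-2.44 ± 0.20), and the proliferation marker MKI67 fell too (-0.84 ± 0.15). SMAD7, an inhibitor of the pathway, rose by 0.87 ± 0.14. The transcription factor gene SNAI2 rose by 0.48 ± 0.12, a call lost under library totals alone at an adjusted p of 0.193, without Mock control 1 at an adjusted p of 0.174, without Mock TGF-β 1 at an adjusted p of 0.0583 or without Mock TGF-β 2 at an adjusted p of 0.105. HSPA1A, an inducible HSP70 whose near-identical copy HSPA1B shares its reads, fell (-0.35 ± 0.11, a call lost without Mock control 1 at an adjusted p of 0.106, without Mock control 2 at an adjusted p of 0.18, without Mock TGF-β 1 at an adjusted p of 0.291, after thinning to the lowest total at an adjusted p of 0.0589 or with only the 4 libraries compared at an adjusted p of 0.0557). FN1 rose by 0.87 ± 0.14, a call lost by limma-trend on the deposited log2 CPM (adjusted p = 0.0553). CDH1, encoding E-cadherin, was at or below 1.17 CPM in every library and had a log2 change of 1.38 ± 0.57, and VIM, with 24.3% of its exonic bases shared with another gene, had 0.14 ± 0.11; neither passed (adjusted p = 0.141 and 0.491, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

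Among TGF-β and SMAD target genes, 29 of 41 rose and 1 fell (30 and 2 adjusted over the list alone). The SMAD target median log2 change was 0.94 (camera adjusted p = 3.60e-50, adjusted p = 0.00153 with an estimated correlation). Members included IL11, an interleukin, at 2.68 ± 0.11, the metalloprotease gene ADAM19 at 2.40 ± 0.12, TGFBI at 2.41 ± 0.14 and LTBP2 at 2.05 ± 0.13. Of the extracellular matrix genes, 25 of 45 rose and 1 fell (28 and 2 adjusted over the list alone). The matrix gene median log2 change was 0.55, or 0.29 under library totals alone (camera adjusted p = 2.49e-16, adjusted p = 0.175 with an estimated correlation). They included the collagen genes COL4A1 1.66 ± 0.14, COL4A2 1.16 ± 0.12, COL1A1 1.19 ± 0.13 and COL7A1 1.14 ± 0.12. Of the actin and contractile genes, 26 of 40 rose and 1 fell (30 and 2 adjusted over the list alone). The actin list median log2 change was 0.50, or 0.24 under library totals alone (camera adjusted p = 1.26e-14, adjusted p = 0.105 with an estimated correlation). RHOB, a small GTPase, rose by 1.79 ± 0.13 and the smooth muscle actin ACTG2 by 1.11 ± 0.14. In the YAP-TEAD target list 11 of 23 rose and 1 fell (12 and 2 adjusted over the list alone). The YAP-TEAD list median log2 change was 0.27, or 0.01 under library totals alone (camera adjusted p = 6.68e-08, adjusted p = 0.0886 with an estimated correlation). Members included CCN2 2.05 ± 0.15, ANKRD1 2.09 ± 0.18 and GADD45B 1.53 ± 0.10. CCN2 is also in the SMAD target list, and 5 of the 23 YAP-TEAD genes are in another list, so the lists are not independent. The unfolded protein and amino acid stress list had 15 rises among 32 genes (23 adjusted over the list alone). The stress response median log2 change was 0.44, or 0.18 under library totals alone (camera adjusted p = 3.37e-11, adjusted p = 0.105 with an estimated correlation). VLDLR 0.98 ± 0.13, SESN2 0.78 ± 0.11 and DNAJB9 1.12 ± 0.17 rose. Of the matrix proteases and inhibitors, 11 of 33 rose (14 adjusted over the list alone). The protease list median log2 change was 0.31, or 0.18 without Mock TGF-β 2, or 0.05 under library totals alone (camera adjusted p = 9.59e-09, adjusted p = 0.175 with an estimated correlation). Members included the protease inhibitor SERPINE2 at 2.42 ± 0.10 and the fibroblast protease FAP at 1.12 ± 0.13.

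TGF-β ligands and receptors had 11 rises and 4 falls among 36 genes (12 and 5 adjusted over the list alone). The ligand and receptor median log2 change was 0.16, or 0.10 without Mock control 1 and 0.10 without Mock TGF-β 2, turning to -0.11 under library totals alone (camera adjusted p = 5.24e-06, adjusted p = 0.105 with an estimated correlation). FSTL3 1.65 ± 0.09, GDF6 1.92 ± 0.12 and INHBA 1.74 ± 0.11 rose. The ligand list holds LEFTY2, at 0 in Mock control; with LEFTY2 at its bound the ligand median was 0.16. Of the mesenchymal list, 11 of 26 rose and 5 fell (11 and 5 adjusted over the list alone). The mesenchymal median log2 change was 0.12, or 0.06 without Mock TGF-β 1 and 0.18 without Mock TGF-β 2, turning to -0.14 under library totals alone (camera adjusted p = 0.00155, adjusted p = 0.175 with an estimated correlation). In it TCF4 rose by 1.79 ± 0.19 and the integrin gene ITGA5 by 1.12 ± 0.11, while S100A4, a mesenchymal marker, fell (-0.94 ± 0.11). Epithelial junction and keratin genes had 6 rises and 1 fall among 21 genes (6 and 2 adjusted over the list alone). The epithelial median log2 change was 0.17, or 0.37 without Mock control 2, turning to -0.09 under library totals alone (camera adjusted p = 0.00567, adjusted p = 0.105 with an estimated correlation). Among the rises were KRT17 1.81 ± 0.10, DSP 1.65 ± 0.16 and KRT14 0.89 ± 0.13. Of the cadherin superfamily, 9 of 38 rose and 5 fell (10 and 6 adjusted over the list alone). The cadherin list median log2 change was 0.39, or 0.25 without Mock control 1 and 0.25 without Mock TGF-β 2, or 0.13 under library totals alone (camera adjusted p = 0.00189, adjusted p = 0.622 with an estimated correlation and 0.109 by fry). The cadherin list call was lost without Mock control 1 (camera adjusted p = 0.0527). Members included CELSR1 1.08 ± 0.12 and CDH6 0.93 ± 0.11.

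Of the G1-S and DNA replication genes, 44 of 50 fell (1 that rose and 47 that fell adjusted over the list alone). The G1-S list median log2 change was -0.86 (camera adjusted p = 2.11e-47, adjusted p = 0.105 with an estimated correlation). The replication factor gene GINS2 (ENSG00000131153.9, chromosome 16, 85676198 to 85690073, minus strand) fell from 39.1 and 30.8 CPM in the Mock control libraries to 13.9 and 11.1 CPM with TGF-β, or -1.49 ± 0.14 on the log2 scale, beside MCM3 -1.10 ± 0.10 and PCNA -1.05 ± 0.10. Of the G2-M and mitosis genes, 47 of 50 fell (49 adjusted over the list alone). The G2-M list median log2 change was -0.64 (camera adjusted p = 3.34e-36, adjusted p = 0.0886 with an estimated correlation). Members included KIF15 -1.13 ± 0.12, NUF2 -0.99 ± 0.11, TOP2A -0.88 ± 0.10 and KIF11 -0.81 ± 0.10. Interferon-stimulated genes had 1 rise and 7 falls among 41 genes (1 and 11 adjusted over the list alone). The interferon list median log2 change was -0.56 (camera adjusted p = 9.35e-04, adjusted p = 0.555 with an estimated correlation and 0.109 by fry). PARP14 and IFIT3 fell (-0.98 ± 0.17 and -1.15 ± 0.21). The inflammatory list was not called (camera adjusted p = 0.203), with 3 rises and 6 falls among 29 genes (5 and 8 adjusted over the list alone): the cytokine gene CSF1 fell (-1.23 ± 0.10), as did the chemokine gene CXCL8 (-1.47 ± 0.17), while PTGS2 rose by 2.35 ± 0.31.

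In all, 2212 of 16008 genes changed with TGF-β in Mock cells, 1172 up and 1040 down (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CDH2 had an adjusted p of 1.39e-05 and BMP6 of 1.00e-08 in this test. The count was 1162 without Mock control 1 and 1143 without Mock TGF-β 2. Scaled by library totals alone, 608 rose and 3885 fell, as the median of all genes moved by -0.27.

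The response to TGF-β1 was measured in the same way in HSF2oe cells. CDH2 rose from 481 ± 25.6 to 1010 ± 108 CPM (mean ± SD, n = 2 each), by 1.07 ± 0.11 on the log2 scale, and BMP6 by 4.0 ± 0.20, from 28 and 23 counts to 382 and 332 counts. FOXS1, SNAI1 and ST6GAL2 rose by 3.51 ± 0.38, 2.50 ± 0.36 and 3.25 ± 0.23. IL11 (ENSG00000095752.7, chromosome 19, 55364382 to 55370463, minus strand) rose by 2.60 ± 0.10. MMP13 rose by 5.17 ± 0.46 and the sulfatase gene SULF2 by 3.22 ± 0.59. SMAD7 rose by 0.48 ± 0.14, or 0.73 without HSF2oe control 1 and 0.26 without HSF2oe control 2, a call lost under library totals alone at an adjusted p of 0.14, under a stricter low-count filter at an adjusted p of 0.0575, by limma-trend on the deposited log2 CPM at an adjusted p of 0.0552, without Mock control 1 at an adjusted p of 0.0566, without Mock control 2 at an adjusted p of 0.0536, without Mock TGF-β 1 at an adjusted p of 0.0523, without Mock TGF-β 2 at an adjusted p of 0.0516, without HSF2oe control 2 at an adjusted p of 0.366, without HSF2oe TGF-β 1 at an adjusted p of 0.275, after thinning to the lowest total at an adjusted p of 0.0552 or with only the 4 libraries compared at an adjusted p of 0.109. SNAI2 rose by 0.56 ± 0.12, a call lost without HSF2oe control 1 at an adjusted p of 0.141 or without HSF2oe TGF-β 2 at an adjusted p of 0.117. Large falls were those of IGFN1 (-2.76 ± 0.23), SECTM1 (-2.46 ± 0.25), TMEM132B (-2.29 ± 0.23), SPTLC3, an enzyme subunit of sphingolipid synthesis (-2.26 ± 0.23), and ANK1 (-2.22 ± 0.20). VIM, CDH1 and HSPA1A did not pass (adjusted p = 0.521, 0.826 and 0.764, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

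Among TGF-β and SMAD target genes, 24 of 41 rose and 1 fell (28 and 1 adjusted over the list alone). The SMAD target median log2 change was 0.81 (camera adjusted p = 1.86e-50, adjusted p = 0.00151 with an estimated correlation). Members included ADAM19 2.44 ± 0.12, CCN2 2.55 ± 0.15 and TGFBI 1.94 ± 0.14. Of the extracellular matrix genes, 19 of 45 rose and 1 fell (21 and 3 adjusted over the list alone). The matrix gene median log2 change was 0.32, or 0.16 under library totals alone (camera adjusted p = 1.24e-09, adjusted p = 0.39 with an estimated correlation and 0.0721 by fry). COL4A1 1.58 ± 0.13, COL1A1 1.08 ± 0.12, COL5A1 1.05 ± 0.13 and COL4A2 0.88 ± 0.12 rose. The actin and contractile list had 21 rises among 40 genes (26 rises and 2 falls adjusted over the list alone). The actin list median log2 change was 0.45, or 0.29 under library totals alone (camera adjusted p = 3.01e-18, adjusted p = 0.155 with an estimated correlation). RHOB and CNN2 rose by 1.91 ± 0.13 and 0.80 ± 0.11. For the stress response list the count was 11 rises among 32 genes (18 adjusted over the list alone). The stress response median log2 change was 0.36, or 0.20 under library totals alone (camera adjusted p = 1.24e-09, adjusted p = 0.155 with an estimated correlation). DNAJB9 and HERPUD1 rose by 1.09 ± 0.17 and 0.92 ± 0.17. Of the YAP-TEAD targets, 9 of 23 rose (10 adjusted over the list alone). The YAP-TEAD list median log2 change was 0.10, or 0.15 without HSF2oe control 1 and -0.01 without HSF2oe TGF-β 1, turning to -0.07 under library totals alone (camera adjusted p = 2.51e-07, adjusted p = 0.122 with an estimated correlation). ANKRD1 2.00 ± 0.17, GADD45B 1.21 ± 0.10 and IGFBP3 1.52 ± 0.26 rose. Ligands and receptors had 7 rises and 6 falls among 36 genes (7 and 7 adjusted over the list alone). The ligand and receptor median log2 change was 0.13, or 0.08 without HSF2oe control 2 and 0.08 without HSF2oe TGF-β 1, turning to -0.03 under library totals alone (camera adjusted p = 0.00252, adjusted p = 0.268 with an estimated correlation). The ligand list holds LEFTY2, which was at 0 in HSF2oe control. With LEFTY2 set to its bound the ligand median was 0.10.

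Of the mesenchymal list, 9 of 26 rose and 3 fell (9 and 4 adjusted over the list alone). The mesenchymal median log2 change was 0.16, turning to -0.0048 under library totals alone (camera adjusted p = 5.96e-04, adjusted p = 0.224 with an estimated correlation). TCF4 and the gelatinase gene MMP2 rose (2.14 ± 0.19 and 0.96 ± 0.13) and S100A4 fell (-0.82 ± 0.11). Epithelial genes had 5 rises and 1 fall among 21 genes (5 and 1 adjusted over the list alone). The epithelial median log2 change was 0.18, or 0.02 without HSF2oe TGF-β 1, or 0.02 under library totals alone (camera adjusted p = 0.00245, adjusted p = 0.155 with an estimated correlation). Members included KRT17 1.80 ± 0.10, DSP 1.84 ± 0.16 and KRT14 0.94 ± 0.14. Of the proteases and inhibitors, 7 of 33 rose (9 that rose and 1 that fell adjusted over the list alone). The protease list median log2 change was 0.06, or 0.14 without HSF2oe control 1 and 0.02 without HSF2oe TGF-β 2, turning to -0.10 under library totals alone (camera adjusted p = 0.00245, adjusted p = 0.441 with an estimated correlation and 0.103 by fry). The protease list call was lost without HSF2oe TGF-β 1 (camera adjusted p = 0.0679). Members included SERPINE2 1.94 ± 0.10 and FAP 0.88 ± 0.13. The G1-S list had 14 falls among 50 genes (1 rise and 23 falls adjusted over the list alone). The G1-S list median log2 change was -0.33 (camera adjusted p = 2.07e-10, adjusted p = 0.438 with an estimated correlation and 0.0878 by fry). BRCA1 -0.54 ± 0.10 and LIG1 -0.50 ± 0.10 fell. Of the G2-M genes, 12 of 50 fell (32 adjusted over the list alone). The G2-M list median log2 change was -0.28, or -0.44 under library totals alone (camera adjusted p = 2.56e-12, adjusted p = 0.224 with an estimated correlation). Members included CDC25B -0.67 ± 0.11 and TOP2A -0.64 ± 0.10. Interferon-stimulated genes had 8 falls among 41 genes (8 adjusted over the list alone). The interferon list median log2 change was -0.46, or -0.70 without HSF2oe TGF-β 1 and -0.25 without HSF2oe TGF-β 2 (camera adjusted p = 7.01e-06, adjusted p = 0.39 with an estimated correlation and 0.0721 by fry). PARP14 fell (-1.01 ± 0.17). CSF1 and CXCL8 fell (-1.17 ± 0.10 and -1.59 ± 0.14) and TNFAIP6 and PTGS2 rose (1.66 ± 0.19 and 2.09 ± 0.26) within an inflammatory list that was not called (camera adjusted p = 0.0942).

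TGF-β changed 1323 genes in HSF2oe cells, 712 up and 611 down (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 596 also rose and 414 also fell in Mock cells, against 52.1 and 39.7 for independent lists, and no gene was called in opposite directions. Both contrasts use the same estimate of each gene's spread, so some overlap beyond these numbers can arise from shared power alone. Across all tested genes, which are not independent, the log2 fold changes of both transfections had a Pearson correlation of 0.52 and a Spearman correlation of 0.51. The count was 673 without HSF2oe control 1, 798 without HSF2oe control 2 and 696 without HSF2oe TGF-β 2, and the genes shared with Mock were 590, 643 and 602 without the same libraries. Scaled by library totals alone, 452 rose and 1593 fell, as the median of all genes moved by -0.17.

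HSF2oe and Mock cells kept without TGF-β were compared to ask what transfection with the HSF2 plasmid changed in untreated cells. CXCL8 (ENSG00000169429.11, chromosome 4, 73740541 to 73743716, plus strand), a neutrophil chemokine, rose from 15.3 ± 1.28 to 83.2 ± 5.56 CPM (mean ± SD, n = 2 each), a log2 fold change of 2.45 ± 0.14. ESM1 (ENSG00000164283.13, chromosome 5, 54977867 to 55022671, minus strand), a secreted proteoglycan, rose by 5.23 ± 0.62, the apoptosis inhibitor gene BIRC3 by 2.37 ± 0.32 and the stress transcription factor gene ATF3 by 2.32 ± 0.25. BMP6 rose by 2.43 ± 0.39, a call lost after thinning to the lowest total at an adjusted p of 0.0681, and H4C8, of a histone family with near-identical copies and so uncertain, by 2.50 ± 0.35. SULF2 fell (-2.68 ± 0.62, a call lost by limma-voom at an adjusted p of 0.0691, without Mock control 2 at an adjusted p of 0.12, without HSF2oe control 1 at an adjusted p of 0.147 or after thinning to the lowest total at an adjusted p of 0.0526). The receptor gene ACKR3 fell too (-2.32 ± 0.42, a call lost without Mock control 2 at an adjusted p of 0.0641 or without HSF2oe control 1 at an adjusted p of 0.0599). IL21R (-2.52 ± 0.29, 23.3% of its exonic bases shared with another gene) and PLXDC1 (-2.46 ± 0.39, or -1.59 without Mock control 2) fell. FABP3, a fatty acid binding protein, fell as well (-2.32 ± 0.30). SMAD7 rose by 0.71 ± 0.14, a call lost without HSF2oe control 1 (adjusted p = 0.0933, the log2 change then at 0.46, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). VIM, CDH2, FN1, MKI67 and HSPA1A did not pass (adjusted p = 0.229, 0.156, 0.692, 0.266 and 0.157, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

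Of the inflammatory and NF-kB target genes, 15 of 29 rose and 1 fell (16 and 1 adjusted over the list alone). The inflammatory median log2 change was 0.74 (camera adjusted p = 4.62e-14, adjusted p = 0.0854 with an estimated correlation). CXCL8 was joined by the cytokine gene IL1B (1.74 ± 0.18) and by TNFAIP3, an NF-kB feedback inhibitor (1.37 ± 0.16). Interferon-stimulated genes had 11 rises and 3 falls among 41 genes (16 and 5 adjusted over the list alone). The interferon list median log2 change was 0.39 (camera adjusted p = 1.52e-04, adjusted p = 0.422 with an estimated correlation and 0.119 by fry). Members included OAS1 at 3.48 ± 0.52 and IFI44 at 1.85 ± 0.34. Of the G1-S genes, 11 of 50 rose (24 adjusted over the list alone). The G1-S list median log2 change was 0.29 (camera adjusted p = 5.26e-10, adjusted p = 0.422 with an estimated correlation and 0.0897 by fry). Cyclin D1 (CCND1) and CLSPN rose by 0.82 ± 0.10 and 0.62 ± 0.10. Of the G2-M genes, 5 of 50 rose (5 adjusted over the list alone). The G2-M list median log2 change was 0.18, or 0.27 under library totals alone (camera adjusted p = 7.77e-05, adjusted p = 0.422 with an estimated correlation and 0.0676 by fry). Members included NUF2 (0.53 ± 0.10). In the YAP-TEAD list 5 of 23 rose and 2 fell (10 and 4 adjusted over the list alone). The YAP-TEAD list median log2 change was 0.16, or 0.10 without Mock control 2 and 0.25 without HSF2oe control 2, or 0.25 under library totals alone (camera adjusted p = 0.0454, adjusted p = 0.422 with an estimated correlation). The YAP-TEAD list call was lost without Mock control 2 (camera adjusted p = 0.0982) or HSF2oe control 2 (camera adjusted p = 0.0849).

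Of the cholesterol synthesis genes, 20 of 25 fell (23 adjusted over the list alone). The cholesterol list median log2 change was -0.55 (camera adjusted p = 2.35e-18, adjusted p = 0.292 with an estimated correlation). LSS, which closes the sterol ring, fell from 442 and 439 CPM in the Mock libraries to 209 and 265 CPM in the HSF2oe libraries (-0.89 ± 0.13 on the log2 scale), beside TM7SF2 -1.29 ± 0.20 and DHCR7 -0.76 ± 0.12. Of the extracellular matrix genes, 23 of 45 fell (2 that rose and 26 that fell adjusted over the list alone). The matrix gene median log2 change was -0.45 (camera adjusted p = 7.73e-14, adjusted p = 0.422 with an estimated correlation and 0.0606 by fry). SERPINH1 -0.84 ± 0.12, COL3A1 -1.15 ± 0.17 and COL15A1 -1.37 ± 0.21 fell. The actin list had 2 rises and 12 falls among 40 genes (4 and 17 adjusted over the list alone). The actin list median log2 change was -0.24, or -0.15 under library totals alone (camera adjusted p = 7.97e-05, adjusted p = 0.422 with an estimated correlation and 0.0796 by fry). RND3 rose (0.83 ± 0.10). Cadherin superfamily genes had 11 falls among 38 genes (15 adjusted over the list alone). The cadherin list median log2 change was -0.47 (camera adjusted p = 3.48e-06, adjusted p = 0.422 with an estimated correlation and 0.0806 by fry). PCDH18 -0.84 ± 0.11, PCDH7 -0.72 ± 0.10 and FAT4 -1.01 ± 0.16 fell. Of the epithelial genes, 7 of 21 fell (1 that rose and 9 that fell adjusted over the list alone). The epithelial median log2 change was -0.33 (camera adjusted p = 0.00271, adjusted p = 0.292 with an estimated correlation). KRT17 fell (-0.66 ± 0.10). The stress response list had 2 rises and 13 falls among 32 genes (2 and 19 adjusted over the list alone). The stress response median log2 change was -0.33 (camera adjusted p = 3.12e-08, adjusted p = 0.292 with an estimated correlation). VLDLR and TRIB3 fell (-1.31 ± 0.14 and -1.03 ± 0.13) while PPP1R15A rose (1.08 ± 0.14). Of the glycolysis and hypoxia genes, 6 of 30 fell (6 adjusted over the list alone). The glycolysis list median log2 change was -0.24, or -0.15 under library totals alone (camera adjusted p = 1.75e-04, adjusted p = 0.422 with an estimated correlation).

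In all, 1937 genes changed, 781 up and 1156 down; CXCL8 had an adjusted p of 1.59e-06 and LSS of 0.00126 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 1252 without Mock control 1, 453 without Mock control 2 and 368 without HSF2oe control 1. Scaled by library totals alone, 1432 rose and 807 fell, so the balance of rises and falls turned with the scaling.

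HSF2oe and Mock cells were compared again in the presence of TGF-β. CXCL8 was 5.99 and 5.12 CPM in the Mock libraries and 31.8 and 23.3 CPM in the HSF2oe libraries, a log2 rise of 2.32 ± 0.17. ESM1, BIRC3 and the transcription factor gene MYB rose by 3.69 ± 0.46, 3.37 ± 0.42 and 2.54 ± 0.28, and the interferon-stimulated gene IFIT1 by 3.13 ± 0.48. The pseudogene RPSAP52, uncertain since it can share reads with similar copies, and the chemokine gene CXCL3 rose by 2.84 ± 0.35 and 2.54 ± 0.39. Falls included the scavenging chemokine receptor ACKR3 (-3.09 ± 0.45), ZNF423 (-3.02 ± 0.28), the sulfatase SULF2 (-3.00 ± 0.36), the matrix protein MGP (-2.95 ± 0.43) and MFAP4 (-2.89 ± 0.38). HSPA1A, whose reads HSPA1B shares, rose by 0.51 ± 0.11. SMAD7, MKI67 and FN1 did not pass (adjusted p = 0.115, 0.062 and 0.0541, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

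Of the G1-S genes, 43 of 50 rose (47 adjusted over the list alone). The G1-S list median log2 change was 0.82 (camera adjusted p = 3.19e-43, adjusted p = 0.192 with an estimated correlation). GINS2 was 32.2 and 30.7 CPM against 13.9 and 11.1 CPM in Mock TGF-β, a log2 rise of 1.34 ± 0.14, beside CLSPN 1.26 ± 0.11, UHRF1 1.06 ± 0.10 and FEN1 0.99 ± 0.10. Of the G2-M genes, 39 of 50 rose (46 adjusted over the list alone). The G2-M list median log2 change was 0.52 (camera adjusted p = 1.59e-21, adjusted p = 0.192 with an estimated correlation). Members included NUF2 0.98 ± 0.11, KIF11 0.77 ± 0.10 and BUB1B 0.73 ± 0.10. Heat shock proteins and cochaperones had 19 rises and 5 falls among 56 genes (24 and 7 adjusted over the list alone). The heat shock median log2 change was 0.23, or 0.42 under library totals alone (camera adjusted p = 1.67e-04, adjusted p = 0.247 with an estimated correlation). HSPA6 rose by 2.18 ± 0.33 and HSP90AA1 by 0.56 ± 0.10, and HSPB7 fell (-0.85 ± 0.14). Inflammatory genes had 14 rises and 1 fall among 29 genes (18 and 1 adjusted over the list alone). The inflammatory median log2 change was 0.67 (camera adjusted p = 2.26e-09, adjusted p = 0.192 with an estimated correlation). TNFAIP3 rose by 1.43 ± 0.17. Of the interferon-stimulated genes, 13 of 41 rose and 5 fell (14 and 5 adjusted over the list alone). The interferon list median log2 change was 0.53, or 0.34 without HSF2oe TGF-β 1 (camera adjusted p = 0.0114, adjusted p = 0.566 with an estimated correlation and 0.192 by fry). The interferon list call was lost without HSF2oe TGF-β 1 (camera adjusted p = 0.204). MX1 and OAS1 rose by 2.53 ± 0.42 and 3.54 ± 0.64.

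Of the extracellular matrix genes, 34 of 45 fell (37 adjusted over the list alone). The matrix gene median log2 change was -0.65 (camera adjusted p = 4.44e-20, adjusted p = 0.247 with an estimated correlation). Members included SERPINH1 -1.0 ± 0.12, COL5A3 -0.96 ± 0.12, LOXL1 -0.92 ± 0.12 and COL5A2 -0.95 ± 0.12. Of the cholesterol synthesis genes, 21 of 25 fell (22 adjusted over the list alone). The cholesterol list median log2 change was -0.55, or -0.36 under library totals alone (camera adjusted p = 4.43e-13, adjusted p = 0.269 with an estimated correlation). Members included TM7SF2 -1.60 ± 0.21, DHCR7 -0.85 ± 0.12 and LSS -0.88 ± 0.13. Cadherin superfamily genes had 16 falls among 38 genes (22 adjusted over the list alone). The cadherin list median log2 change was -0.66, or -0.39 without Mock TGF-β 2 (camera adjusted p = 7.73e-09, adjusted p = 0.318 with an estimated correlation). PCDH7 -1.31 ± 0.10, PCDH18 -0.84 ± 0.11 and FAT4 -1.20 ± 0.18 fell. Of the actin genes, 5 of 40 rose and 20 fell (5 and 22 adjusted over the list alone). The actin list median log2 change was -0.30, or -0.10 under library totals alone (camera adjusted p = 5.81e-04, adjusted p = 0.428 with an estimated correlation). Members included PDLIM7 -0.73 ± 0.10 and MYH10 -1.57 ± 0.25. Ligands and receptors had 3 rises and 14 falls among 36 genes (4 and 16 adjusted over the list alone). The ligand and receptor median log2 change was -0.33, or -0.14 under library totals alone (camera adjusted p = 0.00475, adjusted p = 0.288 with an estimated correlation). GDF6 -1.04 ± 0.11, BMP1 -0.73 ± 0.10 and FSTL3 -0.67 ± 0.09 fell. Of the stress response list, 2 of 32 rose and 19 fell (2 and 22 adjusted over the list alone). The stress response median log2 change was -0.44, or -0.25 under library totals alone (camera adjusted p = 2.26e-09, adjusted p = 0.192 with an estimated correlation). Members included the serine synthesis enzyme PHGDH (-0.90 ± 0.12) and VLDLR (-1.81 ± 0.14). Epithelial genes had 1 rise and 9 falls among 21 genes (1 and 10 adjusted over the list alone). The epithelial median log2 change was -0.45, or -0.25 under library totals alone (camera adjusted p = 0.0109, adjusted p = 0.192 with an estimated correlation). JUP fell (-0.88 ± 0.13).

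Among the integrins, 1 of 16 rose and 3 fell (1 and 4 adjusted over the list alone). The integrin median log2 change was -0.31, or -0.19 without Mock TGF-β 2 and -0.12 without HSF2oe TGF-β 2, or -0.12 under library totals alone (camera adjusted p = 0.043, adjusted p = 0.566 with an estimated correlation and 0.166 by fry). The integrin call was lost without Mock TGF-β 2 (camera adjusted p = 0.0734), HSF2oe control 1 (camera adjusted p = 0.0712), HSF2oe control 2 (camera adjusted p = 0.0713), HSF2oe TGF-β 2 (camera adjusted p = 0.507) or with the replicate block (camera adjusted p = 0.0775). ITGA11 and ITGA1 fell (-1.31 ± 0.12 and -1.28 ± 0.15). ITGB4 was at 0 in HSF2oe TGF-β, and the integrin median was -0.22 with it at its bound. Of the proteases and inhibitors, 5 of 33 rose and 11 fell (6 and 13 adjusted over the list alone). The protease list median log2 change was -0.23, or -0.09 without Mock TGF-β 2, or -0.04 under library totals alone (camera adjusted p = 0.0196, adjusted p = 0.566 with an estimated correlation and 0.108 by fry). The protease list call was lost without Mock TGF-β 2 (camera adjusted p = 0.0637) or HSF2oe TGF-β 2 (camera adjusted p = 0.384). ADAMTS12 -0.83 ± 0.10, ADAMTS14 -1.72 ± 0.23 and MMP11 -2.10 ± 0.31 fell. Glycolysis and hypoxia genes had 9 falls among 30 genes (9 adjusted over the list alone). The glycolysis list median log2 change was -0.17, or -0.06 without HSF2oe TGF-β 1, turning to 0.02 under library totals alone with a camera adjusted p of 0.11 (camera adjusted p = 0.0237, adjusted p = 0.566 with an estimated correlation). The glycolysis list call was lost without HSF2oe TGF-β 1 (camera adjusted p = 0.0874).

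In all, 3449 genes changed, 1537 up and 1912 down (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment); the count was 1509 without Mock TGF-β 2 and 1633 without HSF2oe TGF-β 1. Scaled by library totals alone, 3526 rose and 1073 fell, and the median of all genes moved by 0.19. Shared with the untreated contrast were 525 rises and 903 falls, against 75 and 138 for independent lists, with 1 gene in opposite directions. Here too the shared estimate of the spread can add to the overlap. Across genes, which are not independent, the Pearson correlation was 0.57 and the Spearman correlation 0.62. Without single libraries the shared genes numbered 403 (Mock control 2), 917 (Mock TGF-β 2), 342 (HSF2oe control 1) and 892 (HSF2oe TGF-β 1).

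**Figure D2:**
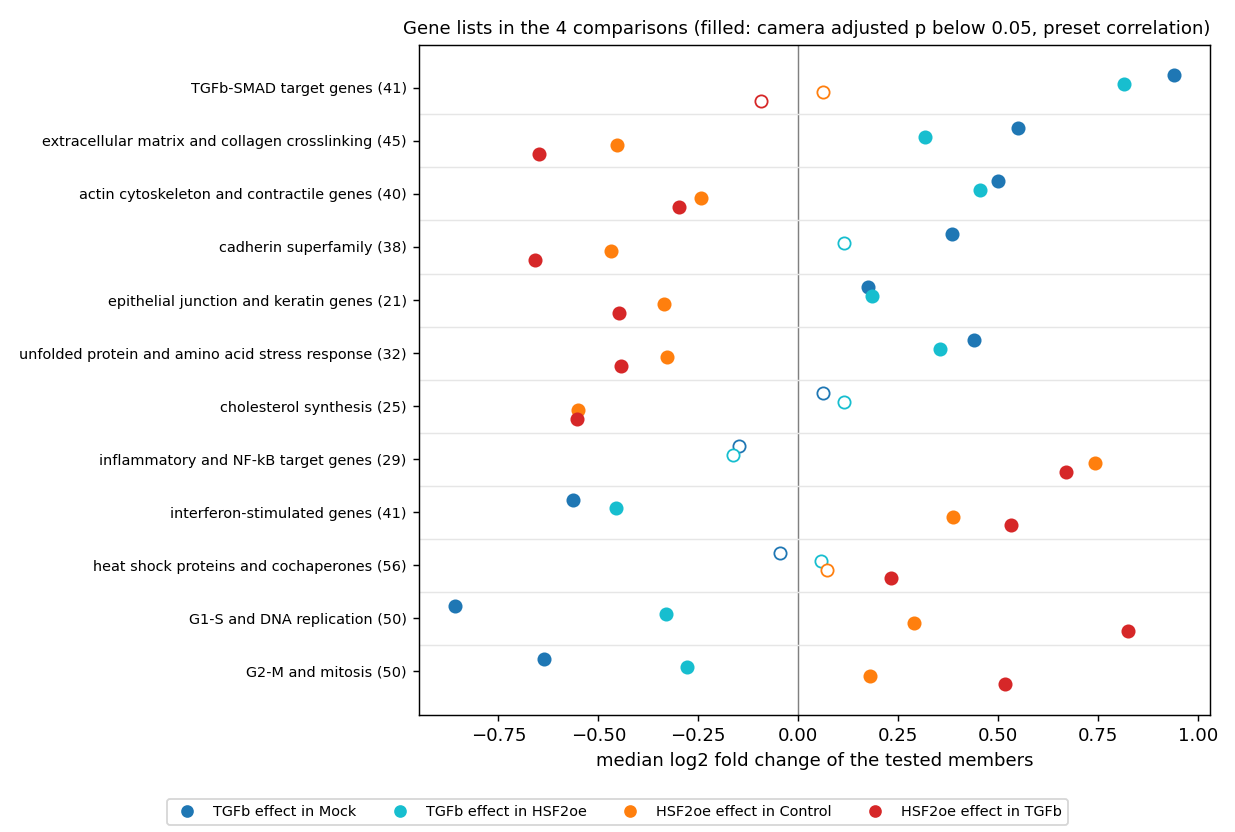
Median log2 fold change of 12 gene lists (vertical axis) in the 4 pairwise comparisons (horizontal axis in log2 units); filled points have a camera adjusted p under 0.05 with the preset correlation. The G1-S list lay at -0.86 with TGF-β in Mock cells and at 0.82 for HSF2oe over Mock with TGF-β.

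Whether HSF2oe changed the response to TGF-β was tested as the difference of both TGF-β effects. BMP6 had the smallest adjusted p: its log2 rise was 7.02 ± 0.26 in Mock and 4.0 ± 0.20 in HSF2oe cells, a difference of -3.01 ± 0.41 that stayed above the threshold (adjusted p = 0.0873, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). GINS2 fell by 1.49 ± 0.14 in Mock cells, and its difference of 1.2 ± 0.19 did not pass (adjusted p = 0.165, same test). No single gene passed over all 16008 genes by edgeR (0 genes, 977 at unadjusted p under 0.05), with 23 by DESeq2, 0 by limma-voom and 0 by limma-trend. The same edgeR test called 83 without a low-count filter and 78 with the replicate number as a block. Among the named-gene results of this contrast, 16 gained a call without a filter, 18 with the block and 6 by DESeq2. SNAI1 and CDH2 differed by 0.01 ± 0.33 and -0.11 ± 0.15 (adjusted p = 0.998 and 0.945, same test). The standard error of the SNAI1 difference does not exceed that of its TGF-β effect in HSF2oe cells alone. It is therefore too small and does not show that both SNAI1 responses were equal. As a list, G1-S genes had a smaller fall in HSF2oe cells: the median difference was 0.54, and 35 of 50 passed adjusted over the list alone (camera adjusted p = 9.81e-45, adjusted p = 0.261 with an estimated correlation and 0.199 by fry). For G2-M genes it was 0.32, with 9 adjusted over the list alone (camera adjusted p = 3.24e-22, adjusted p = 0.261 with an estimated correlation and 0.105 by fry). Of the G1-S genes 47 of 50 and of the G2-M genes 50 of 50 had the higher log2 change in HSF2oe cells. Camera called 11 of 27 lists here with the preset correlation, and none of these with an estimated correlation or by fry. In simulated counts, 16.1% of 1.5-fold and 75.8% of 2-fold differences were recovered in this contrast, among genes with a mean log2 CPM of at least 1. Most differences of the size of these list medians would therefore be missed gene by gene.

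**Figure D3:**
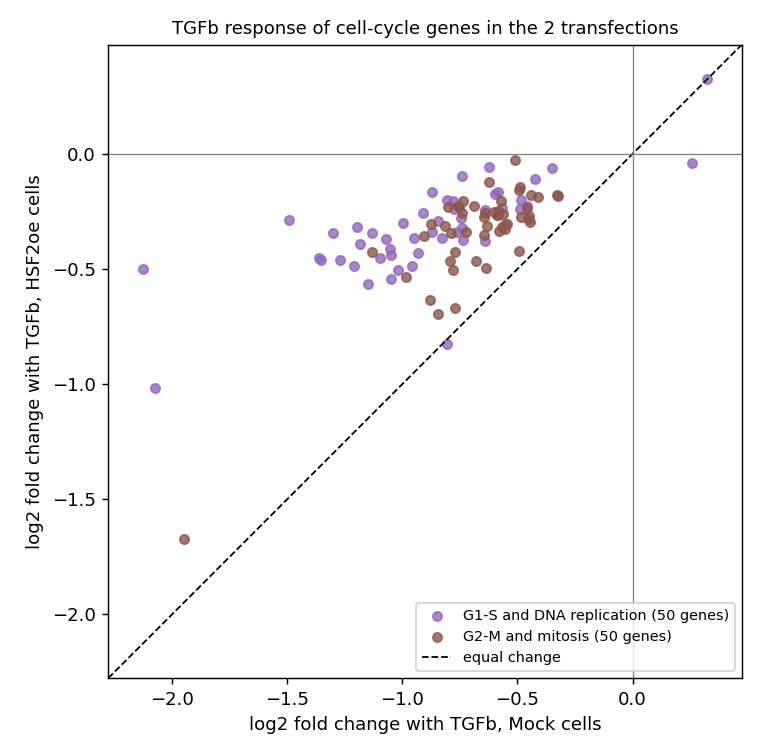
Log2 fold change with TGF-β in Mock cells (horizontal axis) and HSF2oe cells (vertical axis) for the genes of the G1-S and G2-M lists, one point per gene, with a line of equal change. Nearly all points lie above the line: 47 of 50 G1-S genes and 50 of 50 G2-M genes.

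Averaged over both transfections, TGF-β changed 3228 genes, 1624 up and 1604 down, with SNAI1 at 2.50 ± 0.24, CDH2 at 1.13 ± 0.08, FN1 at 0.72 ± 0.10, SMAD7 at 0.67 ± 0.10 and MKI67 at -0.77 ± 0.10 (adjusted p = 1.33e-04 for FN1, 2.41e-04 for SMAD7 and 1.44e-04 for MKI67, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among genes with a mean log2 CPM of at least 1, the largest rises were those of MMP13 5.81 ± 0.34, BMP6 5.51 ± 0.16, ST6GAL2 3.66 ± 0.17, FOXS1 3.62 ± 0.25, SULF2 3.39 ± 0.34 and EGR2 3.10 ± 0.32. The largest falls there were those of LINC01085 -2.77 ± 0.25, SECTM1 -2.53 ± 0.18 and IGFN1 -2.52 ± 0.18, SLC43A3 -2.30 ± 0.22 (29.9% of its exonic bases shared with another gene), TMEM132B -2.25 ± 0.15 and ANK1 -2.19 ± 0.14. Of the TGF-β and SMAD targets 32 of 41 rose and 2 fell (34 and 3 adjusted over the list alone), and of the G2-M genes 49 of 50 fell (50 adjusted over the list alone). Their camera adjusted p were 4.36e-57 and 8.60e-27 (adjusted p = 0.00118 and 0.102 with an estimated correlation). Scaled by library totals alone, 815 rose and 5246 fell, as the median of all genes moved by -0.22.

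Averaged over both treatments, HSF2oe changed 5199 genes, 2431 up and 2768 down (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ESM1 rose by 4.46 ± 0.39, BIRC3 by 2.87 ± 0.26 and CXCL8 by 2.39 ± 0.11, and SFRP4, a secreted Wnt antagonist, fell (-2.43 ± 0.20). RPSAP52, CXCL3 and the phosphatase gene DUSP4 rose by 2.38 ± 0.22, 2.37 ± 0.24 and 2.23 ± 0.31. SULF2, ACKR3 and PLXDC1 fell (-2.84 ± 0.35, -2.70 ± 0.31 and -2.45 ± 0.27), as did IL21R (-2.63 ± 0.20, 23.3% of its exonic bases shared with another gene). HSPA1A rose by 0.37 ± 0.07 (adjusted p = 0.00196) and SMAD7 by 0.52 ± 0.10 (adjusted p = 0.00143, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the heat shock proteins and cochaperones 23 of 56 rose and 7 fell (24 and 7 adjusted over the list alone). The heat shock median log2 change was 0.16, or 0.30 under library totals alone (camera adjusted p = 0.00186, adjusted p = 0.356 with an estimated correlation). With the preset correlation, camera called this list for HSF2oe over Mock with TGF-β but not without it. Without TGF-β the list median ran from 0.05 to 0.11 when single libraries were left out. HSPA6 rose by 2.06 ± 0.23. Of the cholesterol synthesis genes 23 of 25 fell (24 adjusted over the list alone). The cholesterol list median log2 change was -0.54 (camera adjusted p = 2.43e-17, adjusted p = 0.243 with an estimated correlation). Scaled by library totals alone, 4438 rose and 1693 fell, as the median of all genes moved by 0.14.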

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

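Thinning, the list fits under RLE and without single libraries, and the tests of the blood markers, of shifts of all genes alike and of rises that held whichever library was left out were chosen only after the results were seen. By camera on the difference of both TGF-β effects, 11 lists passed with the preset correlation, none of them with an estimated one (lowest adjusted p = 0.261) or by fry (lowest adjusted p = 0.105). The G1-S and G2-M lists had medians of 0.54 and 0.32 in this difference, since they fell less with TGF-β in HSF2oe cells (medians -0.33 and -0.28) than in Mock cells (-0.86 and -0.64). The lower quartile of the members stayed above 0, at 0.20 or higher whichever library was left out, which argues against a single library as the whole cause. After thinning it was at 0.21 or higher, but thinning hardly moves fold changes of genes with many counts, so this decided little about depth. A lower quartile of 0.22 or higher under RLE and library totals decided nothing, since these moved the median of all genes by -0.00135 and by 0.10, the latter toward the lists. The lower list median under these scalings, 0.32, exceeded the larger shift by more than 2 standard errors of 0.06. That standard error treats the list members as independent, so the margin is smaller for correlated genes. The lists thus moved more than the median of all genes. This was plain from the main medians already, and neither scaling moved all genes clearly against the lists, so it is no separate evidence on scaling. Depth and scaling stay open. A weaker response of cell cycle genes to TGF-β in HSF2oe cells may be one biological reading, a hypothesis found on these data and without a call at an estimated correlation or by fry.

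Other lists passed the same test of the difference with the preset correlation alone. Matrix proteases and inhibitors had a median of -0.21, or -0.32 without Mock TGF-β 1, or -0.11 under library totals alone (camera adjusted p = 8.26e-06, adjusted p = 0.453 with an estimated correlation and 0.402 by fry). Mitochondrially encoded genes had a median of -0.43, or -0.22 without HSF2oe control 1, -0.80 without HSF2oe TGF-β 1 and -0.09 without HSF2oe TGF-β 2 (camera adjusted p = 3.16e-05, adjusted p = 0.698 with an estimated correlation and 0.68 by fry), a call lost without HSF2oe TGF-β 2 (camera adjusted p = 0.652). Extracellular matrix genes had a median of -0.19, or -0.11 without Mock control 1, -0.31 without Mock control 2 and -0.09 without Mock TGF-β 2, or -0.09 under library totals alone (camera adjusted p = 3.30e-05, adjusted p = 0.698 with an estimated correlation and 0.68 by fry), a call lost without Mock control 1 (camera adjusted p = 0.224) or Mock TGF-β 2 (camera adjusted p = 0.0709). Heat shock proteins had a median of 0.12, or 0.22 under library totals alone (camera adjusted p = 0.00161, adjusted p = 0.453 with an estimated correlation and 0.199 by fry). Ribosomal protein genes had a median of 0.092, or 0.03 without Mock control 1, 0.20 without Mock control 2, 0.18 without Mock TGF-β 1, 0.02 without Mock TGF-β 2 and 0.15 without HSF2oe control 2, or 0.19 under library totals alone (camera adjusted p = 0.00185, adjusted p = 0.908 with an estimated correlation and 0.797 by fry), a call lost without Mock control 1 (camera adjusted p = 0.712), Mock TGF-β 2 (camera adjusted p = 0.817) or HSF2oe control 1 (camera adjusted p = 0.133). TGF-β and SMAD targets had a median of -0.16, or -0.05 under library totals alone (camera adjusted p = 0.00402, adjusted p = 0.261 with an estimated correlation and 0.105 by fry). Cadherin superfamily genes had a median of -0.23, or -0.06 without Mock control 1, -0.37 without Mock control 2, -0.15 without Mock TGF-β 2, -0.11 without HSF2oe control 1, -0.36 without HSF2oe TGF-β 1 and -0.11 without HSF2oe TGF-β 2, or -0.14 under library totals alone (camera adjusted p = 0.00607, adjusted p = 0.698 with an estimated correlation and 0.68 by fry), a call lost without Mock control 1 (camera adjusted p = 0.458), Mock TGF-β 2 (camera adjusted p = 0.247), HSF2oe control 1 (camera adjusted p = 0.0621) or HSF2oe TGF-β 2 (camera adjusted p = 0.225). Ligands and receptors had a median of -0.17, or -0.04 without Mock control 1, -0.08 without Mock TGF-β 2 and -0.10 without HSF2oe TGF-β 2, or -0.07 under library totals alone (camera adjusted p = 0.0122, adjusted p = 0.453 with an estimated correlation and 0.402 by fry), a call lost without Mock control 1 (camera adjusted p = 0.182), Mock TGF-β 2 (camera adjusted p = 0.128), HSF2oe control 1 (camera adjusted p = 0.0621) or HSF2oe TGF-β 2 (camera adjusted p = 0.123). Integrins had a median of -0.15, or -0.26 without Mock control 2, -0.27 without Mock TGF-β 1, -0.01 without HSF2oe control 1, -0.40 without HSF2oe control 2 and -0.39 without HSF2oe TGF-β 1, or -0.06 under library totals alone (camera adjusted p = 0.0289, adjusted p = 0.698 with an estimated correlation and 0.68 by fry), a call lost without Mock control 1 (camera adjusted p = 0.2), Mock TGF-β 2 (camera adjusted p = 0.247), HSF2oe control 1 (camera adjusted p = 0.76) or HSF2oe TGF-β 2 (camera adjusted p = 0.594).

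Inflammatory and interferon-stimulated genes were higher in HSF2oe cells, with medians of 0.72 and 0.62 in the averaged effect (camera adjusted p = 1.26e-12, adjusted p = 0.151 with an estimated correlation, and for the interferon list camera adjusted p = 0.00109, adjusted p = 0.467 with an estimated correlation and 0.0702 by fry); the planned bound on their lower quartile decided nothing, since it reached -0.00101 under other scalings and -0.12 without single libraries, in lists whose members go both ways. The lower list median under other scalings, 0.61, stayed above the largest shift of all genes (0.14) by barely more than 2 standard errors of 0.24. That standard error treats the list members as independent, so this margin does not decide on a shift of all genes alike. Of the members, 27 of 70 rose past the threshold whichever library was left out (34 with all libraries), although the interferon median fell to 0.41 without HSF2oe TGF-β 1. The 8 tested of 22 blood and endothelial markers had a median of -0.39, or -0.25 without Mock control 2. They reached at most 15.4 CPM for CSF1R and 0.681 CPM for PTPRC. HS578T is an established cell line, so a test for such cells could hardly come out otherwise and decides little. A response to the HSF2 plasmid or to its protein may be one reading, and the design does not separate plasmid from protein. Scaling stays open, as do single libraries as part of the cause.

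HSF2oe changed 1.78 times as many genes with TGF-β as without it. Thinned to the lowest total the ratio was 1.84. The lowest total was that of Mock TGF-β 1, in the contrast with more calls. Thinning took no counts from that library, so this ratio decided little about depth. Without single libraries the ratio was 0.757 (Mock TGF-β 2), 0.82 (HSF2oe TGF-β 1), 7.34 (Mock control 2) and 8.86 (HSF2oe control 1). Each remaining library, left out singly, gave a ratio between 0.82 and 7.34. A ratio of 1 or less was fixed beforehand as the sign of 1 library, and the ratios without Mock TGF-β 2 and HSF2oe TGF-β 1 met it. However, the contrast that lost a library called fewer genes each time, and each such fit left a group with a lone library. The size of the loss differed between libraries of the same group, and its cause was not tested. These ratios therefore cannot tell whether 1 library accounts for the difference in counts, which stays open.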

How the results depend on the processing

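Thinning and the RLE and leave-one-out fits of lists and overlaps were chosen after the results were seen; the other settings were not. Of 630 calls of named genes, 486 kept their side of the threshold under every setting, and 3 of 91 list calls did. The estimated correlation ended 88 list calls and fry 31. Among the named-gene results, 41 calls were lost and 28 gained under library totals alone, 10 and 4 by limma-trend, 9 and 17 by DESeq2 and 14 and 3 after thinning. Library totals alone gave 4493 genes for TGF-β in Mock cells, 2045 in HSF2oe cells and 6061 averaged; this scaling leaves the composition of the libraries uncorrected. The contrast of both TGF-β effects had 83 genes without a filter and 23 by DESeq2; the cause was not tested. The numbers of the replicates are shared across groups but no label pairs them; same-numbered libraries deviated together with correlations of 0.0498 to 0.163 between pairs of groups. With the replicate block the counts were 3350 and 2366 for TGF-β in Mock and HSF2oe cells, 3614 for HSF2oe in control cells and 78 for the contrast of both effects, and 1777 and 2670 genes were shared by the TGF-β and the HSF2oe effects. Leaving out 1 library gave 1143 to 2266 genes for TGF-β in Mock cells, 673 to 1334 in HSF2oe cells, 368 to 1993 for HSF2oe in control cells and 1509 to 3331 with TGF-β, and 590 to 839 and 342 to 1396 shared genes. The mitochondrial list in TGF-β-treated HSF2oe cells turned to -0.40 without HSF2oe TGF-β 1 (range -0.40 to 0.38). For the cholesterol list in the contrast of both effects, the direction of the camera test reversed without HSF2oe control 2. Its median there was 0.20 (range -0.14 to 0.20), and the reversal is that of the test direction. The cause was not tested. Depth limits the low genes: BMP6 had 4 and 5 counts in Mock control.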

Other observations

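The list members named here and the contrast each list is described in were chosen after their values were seen, while the lists and both fits of other splits were fixed before. The lists below concern the HSF2oe effect averaged over treatments. The p53 target list had 6 rises and 7 falls among 25 genes (6 and 7 adjusted over the list alone). The p53 target median log2 change was -0.06, from -0.11 to -0.02 without 1 library each, turning to 0.08 under library totals alone (camera adjusted p = 0.691, adjusted p = 0.825 with an estimated correlation). GADD45A, a growth arrest gene, and PMAIP1, encoding NOXA, rose by 1.13 ± 0.08 and 1.02 ± 0.12, and TP53INP1 fell (-0.92 ± 0.15). Among NRF2 and metallothionein genes there were 5 rises and 8 falls among 24 genes (7 and 11 adjusted over the list alone). The NRF2 list median log2 change was -0.18, or -0.12 without Mock control 1, or -0.04 under library totals alone (camera adjusted p = 0.36, adjusted p = 0.825 with an estimated correlation). Members included MT2A, a metallothionein, at 1.2 ± 0.13 and AKR1C3 at -1.29 ± 0.13. Luminal breast markers had 2 rises and 5 falls among 10 genes (3 and 5 adjusted over the list alone). The luminal median log2 change was -0.32, or -0.19 without Mock control 1, or -0.18 under library totals alone (camera adjusted p = 0.674, adjusted p = 0.825 with an estimated correlation). Members included the transcription factor genes TBX3 at 0.77 ± 0.09 and GATA3 at 0.77 ± 0.10, while MUC1 fell (-0.73 ± 0.13). The proteasome list had 5 rises and 5 falls among 43 genes (4 and 5 adjusted over the list alone). The proteasome median log2 change was 0.04, or 0.06 without Mock control 1, 0.02 without Mock control 2 and 0.06 without Mock TGF-β 1, or 0.18 under library totals alone (camera adjusted p = 0.836, adjusted p = 0.942 with an estimated correlation). The falls included PSMB9 and PSME1, subunits of the immunoproteasome and its activator (-1.17 ± 0.15 and -0.49 ± 0.07), and PSMD2 rose by 0.50 ± 0.07. Heat shock factors and their partners had a median log2 change of 0.01, from -0.0037 to 0.05 without 1 library each, or 0.15 under library totals alone (camera adjusted p = 0.895, adjusted p = 0.958 with an estimated correlation), and meiosis and germ cell genes had a median log2 change of -0.13, or -0.08 without Mock TGF-β 1 and -0.05 without HSF2oe control 1, turning to 0.01 under library totals alone (camera adjusted p = 0.837, adjusted p = 0.942 with an estimated correlation). Blood and endothelial markers had a median log2 change of -0.39, or -0.25 without Mock control 2, or -0.25 under library totals alone (camera adjusted p = 0.166, adjusted p = 0.366 with an estimated correlation), where CD14 fell (-1.30 ± 0.27); in the p53, proteasome, heat shock factor and meiosis lists the median, mean and test differ in sign.

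With TGF-β in HSF2oe cells, ribosomal protein genes had a median log2 change of 0.14, turning to -0.02 under library totals alone (camera adjusted p = 1.33e-04, adjusted p = 0.767 with an estimated correlation and 0.223 by fry). With TGF-β in Mock cells, mitochondrially encoded genes had a median log2 change of 0.41, or 0.15 under library totals alone (camera adjusted p = 0.00408, adjusted p = 0.648 with an estimated correlation and 0.329 by fry). The share of counts from mitochondrial genes ranged from 2.86% in HSF2oe TGF-β 2 to 4.74% in HSF2oe TGF-β 1. PTPRC, a blood cell marker, was at 0 in both HSF2oe TGF-β libraries, at least 3.7-fold lower than in HSF2oe control, with a floor of 3 counts per library.

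Other splits of the 8 libraries into 4 and 4 were fitted for the averaged effects. Fitted as 2 groups alone, TGF-β called 970 genes, and 2 of 35 splits called as many, the other being the split by transfection with 2416; chance cannot be excluded by this count. For HSF2oe the same fit called 2416 genes, reached by 1 of 35 splits, the real one, with 970 for the split by treatment as the highest other. With the other factor kept in the fit, the effects of TGF-β and HSF2oe called 3183 and 5141 genes. In these fits, and for HSF2oe fitted as 2 groups, only the 18 splits balanced over the other factor can stand in for the real one, a restriction made after the results were seen, and these are too few for a share under 0.05. With the other factor kept, 1 of them, the real one, gave as many genes in each fit. The highest other of the 18 called 0 and 0 genes by edgeR, with at most 1518 and 2058 at unadjusted p under 0.05, and no other tool was run on splits. The split equal to the other factor could not be fitted when that factor was kept.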
